A study of Homo sapiens with 8 samples.

How the data were processed

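THP-1 cells, untreated or irradiated with 20 Gy, were profiled on 8 Affymetrix arrays of 54675 probe sets. Total RNA was isolated with spin columns and labelled by a single amplification cycle with biotin, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and array, and per the submitters' processing notes the software was GCOS 1.4.0.036. The scaling target, the background steps and detection calls are not given in the sources used here. A low signal is therefore not read as absence. Groups were taken from the labels: irradiated day 7 (3 arrays), irradiated day 3 (1), untreated day 7 (2) and untreated day 0 (2).

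From the deposited intensities, each array was scaled to a mean of 500 after trimming 2% of probe sets at each end, 32 was added and log2 was taken. Fold changes are on the log2(signal + 32) scale, which understates the change of low genes. The 62 control probe sets were left out of the tests. Of the probe sets, 41091 carried 1 gene symbol in the platform annotation, 1801 several and 11721 none, and only those with 1 were named. Of the 41091, 41037 matched the RefSeq table by Entrez number, and 0 symbols needed an update. For a gene with several probe sets, the one with the highest mean log2 signal over the 8 arrays was used, and disagreement in sign between probe sets is stated. Of 19775 genes, 14649 had a scaled signal of at least 100 on at least 2 arrays and were tested.

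Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes (trend of variance on signal), and Benjamini-Hochberg adjustment with a threshold of 0.05. Of the contrasts, 4 came from 1 fit of a mean per group to all 8 arrays, with 4 residual degrees of freedom: irradiated against untreated at day 7, irradiated day 3 against untreated day 0, untreated day 7 against day 0, and the difference between the first 2. All irradiated against all untreated arrays were compared in a fit of 2 groups with 6 residual degrees of freedom. The 30 gene lists, written together with the rule for named genes, were tested with camera at its preset correlation of 0.01, with camera and an estimated correlation, and with fry, adjusted over the lists. A list needed 3 tested genes. With an estimated correlation p-values rose even for some lists whose estimate lay below the preset. A call lost there thus does not by itself show correlated genes. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.

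Genes named in the text followed a rule fixed before the data were examined. For day 7 it took, in each direction, the 12 genes with the largest change among those past the threshold whose arrays did not overlap, or all that passed, filled to 10 as values by the lowest p among genes with an absolute log2 fold change of at least 1. Other comparisons took 6 per direction, filled to 4. Each list gave up to 4 passing members, or otherwise its 2 largest as values. For comparisons other than day 7, members are named only for lists described there, and not all of them. F3, THBD, TFPI, SERPINB2, PLAU, PLAUR, F13A1, F5, PROCR, ANXA5, FGL2, CDKN1A and MKI67 were always named where measured, and a further gene of the rule is not reported here.

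The steps were tested on simulated data with the real genes' means and spreads, with 200 changed genes in each of 5 runs of 14649 genes. For the day 7 comparison 22% of genes changed by 1 on the log2 scale were recovered and 77.6% of those changed by 2, with 6.16% false calls. For all irradiated against all untreated these were 46.8%, 86.8% and 5.91%, and for day 3, 4.8%, 56.6% and 6.92%. A list of 40 genes shifted by 0.5 was found in 5 of 5 runs, and 0 of 145 other lists were called. The simulated genes varied independently of each other. These runs therefore do not show how often camera with the preset correlation calls lists of correlated genes falsely.

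Alternatives were other offsets (8 and 128), quantile normalization, values as deposited, centring on the median, no filter, a mean signal of at least 300, all probe sets, the mean of a gene's probe sets, eBayes without the trend or robust, fits of only the arrays compared, blocks by run, other control arrays, other thresholds, and leaving out each array. Run here means the shared prefix of sample titles, and joined runs are those whose prefixes may mark 1 experiment, which the labels do not state. The GAPDH 3' to 5' ratio as a covariate and the fit without both arrays whose ratio exceeds 2 were added after seeing the data.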

Results

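Gene expression was measured on 8 single-colour oligonucleotide arrays in THP-1 cells, a human monocytic line derived from an acute leukaemia. The cells had received ionizing radiation at 20 Gy or no treatment. Irradiated cells were harvested on day 7 (3 arrays) and day 3 (1 array) after exposure, and untreated cells on day 7 (2 arrays) and day 0 (2 arrays). An untreated sample of day 3 was not analysed here. The series title names procoagulant activity as its subject, so genes of coagulation and of fibrinolysis, the breakdown of clots, were among the 30 gene lists tested. The trimmed mean of the deposited intensities lay between 51.9 and 58.4 on the 8 arrays. The number of arrays limits the precision of every value. The title prefixes differ between the replicates of each group, but the labels do not say that replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

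The arrays differed in a sign of RNA quality, the ratio of the signals of the 3' and the 5' control probe sets of GAPDH. It was 3.06 and 3.19 on irradiated day 7 replicates 1 and 2, and 1.09 on irradiated day 7 replicate 3. On the 4 untreated arrays it lay between 1.02 (untreated day 7 replicate 2) and 1.48 (untreated day 0 replicate 2), and on the day 3 array it was 1.21. The same ratio for ACTB was 2.45, 4.76 and 1.13 on the 3 irradiated day 7 arrays and 0.988 to 1.62 on the untreated arrays. This sign thus moved with irradiation at day 7 on 2 of 3 arrays, and this holds for every gene group of day 7 below. The alternative without both arrays of high ratio leaves 1 irradiated array at day 7, assumed to vary like the other groups. The ratio differed much only among the irradiated day 7 arrays. As a covariate it therefore makes the day 7 comparison rest largely on replicate 3.

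The main comparison set irradiated against untreated cells at day 7. Among the genes that rose were many induced by interferon, the antiviral signalling proteins. IFI44L was 33.8-fold higher in irradiated cells (log2 fold change 5.08 ± 0.46, SE), with a mean scaled signal of 3493 ± 1257 (SD, n = 3) against 88.9 ± 95.7 (SD, n = 2). From so low an untreated signal the fold depends on the offset, and the log2 value was 5.60 with the smaller and 4.08 with the larger of the other offsets. The same holds for every value of a gene with a group mean near or under 100, such as IFIT1, IFI27, CFP, SIGLEC1, ADAM28, FABP4, TP53INP1 and ID1. IFIT1, which binds foreign RNA, rose 16.2-fold and IFI27 16.1-fold. IFI44 rose 14.9-fold, MX1, a GTPase that blocks viral replication, 13.9-fold, and ISG15, a ubiquitin-like modifier, 10.6-fold. IFITM1, a membrane protein that hinders virus entry, rose 10.1-fold and OAS1, a sensor of double-stranded RNA, 9.30-fold. Of 40 measured genes of the fixed interferon response list, 25 rose and 0 fell in limma with Benjamini-Hochberg adjustment over 14649 genes, while 36 rose adjusted over the list alone. The list's mean log2 fold change was 2.08 (camera adjusted p = 3.4e-50, and adjusted p = 0.0772 with an estimated correlation). Between each irradiated and each untreated day 7 array, the list's median log2 difference lay between 1.46 and 2.35. The larger differences were those of replicate 3, the irradiated array with the low 3' to 5' ratio.

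**Figure D1:**
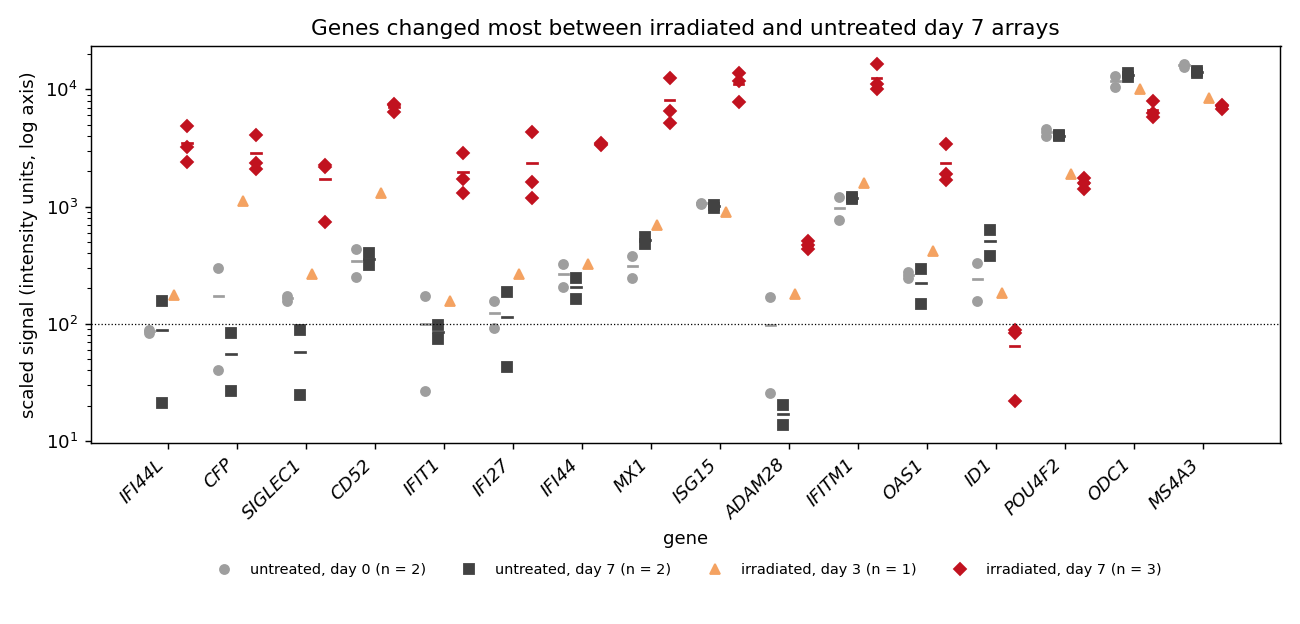
Scaled signal (log axis) of the 16 genes named first by the fixed rule in the day 7 comparison. Each point is 1 array, bars are group means, colours and symbols mark the 4 groups, and the dotted line marks a signal of 100. The 3 irradiated day 7 arrays lie above both untreated day 7 arrays for 12 genes and below them for ID1, POU4F2, ODC1 and MS4A3.

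Other genes with large increases were CFP, SIGLEC1, CD52 and ADAM28. CFP, the complement activator properdin, was 33.3-fold higher (log2 5.06 ± 0.54), SIGLEC1, a macrophage lectin, 18.9-fold (4.24 ± 0.47) and CD52, a surface glycoprotein of leukocytes, 18.3-fold (4.20 ± 0.28). ADAM28, a membrane metalloprotease, rose 10.3-fold. Of 33 measured genes of the monocyte and macrophage maturation list, 7 rose and 0 fell, among them SIGLEC1, the transmembrane glycoprotein GPNMB (8.09-fold), the fatty acid carrier FABP4 (6.94-fold) and the complement receptor VSIG4 (5.01-fold). Adjusted over the list alone, 23 rose and 1 fell. The list's mean log2 fold change was 1.24 (camera adjusted p = 5.66e-18, and adjusted p = 0.0151 with an estimated correlation). Of 12 measured MHC class II genes, which present antigen, 3 rose and 0 fell, namely HLA-DPA1 (4.66-fold), HLA-DRB1 (2.55-fold) and HLA-DQB1 (2.51-fold), and 7 rose adjusted over the list alone (mean log2 1.14, camera adjusted p = 5.77e-09, and adjusted p = 0.0447 with an estimated correlation). Maturation and MHC class II were the 2 of the 30 lists that passed with the estimated correlation at day 7, of 16 that passed with the preset one. HLA genes are near-identical in parts, so single members are uncertain. On 2 of the 3 irradiated arrays these lists, too, were read from RNA with a GAPDH ratio above 3.

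Some lysosomal and adhesion genes rose as well. Of 34 measured lysosomal genes, 4 rose, namely the proteases CTSB (3.44-fold) and CTSH (2.95-fold), the sphingolipid activator precursor PSAP (3.08-fold) and the activator GM2A (2.33-fold). Adjusted over the list alone 14 rose, and 33 of 34 had a positive log2 fold change (mean 0.64, camera adjusted p = 1.74e-12, and adjusted p = 0.113 with an estimated correlation). For GM2A, 2 of 6 probe sets had the other sign. Of 35 adhesion and matrix genes, 3 rose: the gelatinase MMP9 (4.47-fold), the lectin LGALS3 (3.35-fold) and the integrin ITGB7 (2.89-fold). Adjusted over the list alone, 13 rose and 1 fell (mean log2 0.61, camera adjusted p = 3.03e-07, and adjusted p = 0.166 with an estimated correlation). With the GAPDH ratio as a covariate, chosen after seeing the data, CTSB (log2 1.68), CTSH (1.81), MMP9 (2.63) and LGALS3 (1.76) still passed. PSAP (1.20), GM2A (0.92) and ITGB7 (1.48) did not. FABP4 was the 1 of 17 lipid efflux and oxysterol response genes that rose, with 4 adjusted over the list alone (mean log2 0.56, camera adjusted p = 0.00115, and adjusted p = 0.109 with an estimated correlation).

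Few genes passed in the other direction. ID1, an inhibitor of differentiation factors, fell 5.73-fold (log2 -2.52 ± 0.47), from a mean signal of 504 to 64.7. Its log2 value was -2.95 with the smaller and -1.70 with the larger of the other offsets. POU4F2, a transcription factor, fell 2.51-fold, MS4A3, a gene of immature myeloid cells, 1.97-fold, and the polyamine synthesis enzyme ODC1 fell by 1.00 on the log2 scale. A further 6 genes complete the lower side as values, since their adjusted p missed the threshold. They are the growth regulator MYC (log2 -1.26, adjusted p = 0.0536 in limma), GAL (-1.32), ACAT1 (-1.20), ALG1 (-1.27), CENPV (-1.08) and DEFA4 (-1.80). With the GAPDH ratio as a covariate, POU4F2 (log2 -1.33) and MS4A3 (-1.03) still passed and ID1 (log2 -1.996, adjusted p = 0.193 in limma) and ODC1 (log2 -1.02, adjusted p = 0.112) did not. Without both arrays of high ratio none of the 4 passed, with log2 values of -2.11 for ID1, -1.31 for POU4F2, -1.07 for ODC1 and -1.04 for MS4A3.

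Genes of DNA replication had mostly negative values, with no single gene past the threshold. Of 40 S phase genes 38 had a negative log2 fold change and 0 passed, also adjusted over the list alone. The list's mean was -0.51 (camera adjusted p = 6.56e-15, and adjusted p = 0.109 with an estimated correlation), with PRIM1, a primase subunit, at -1.09 ± 0.36 and the helicase subunit MCM7 at -1.02 ± 0.30. Of 42 mitosis genes 0 passed (mean -0.26, camera adjusted p = 1.67e-05, and adjusted p = 0.419 with an estimated correlation), with PLK1 at -0.99 ± 0.31 and CDC25B at 0.82 ± 0.33. MKI67, a proliferation marker, stood at 0.01 ± 0.25, and 3 of its 4 probe sets had the other sign. Of 23 double-strand break repair genes 0 passed (mean -0.22, camera adjusted p = 0.00379, and adjusted p = 0.113 with an estimated correlation), with RAD51D at -0.83 ± 0.60 and EXO1 at -0.72 ± 0.28. With the GAPDH ratio as a covariate the S phase mean was -0.37 and still passed camera (adjusted p = 1.11e-08), with PRIM1 at -0.35, MCM7 at -0.46, EXO1 at -0.33 and RAD51D at -0.05. Without both arrays of high ratio these genes stood at -0.38, -0.48, -0.32 and 0.17.

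Among 26 measured p53 targets, which respond to DNA damage, TP53INP1 (8.62-fold, log2 3.11 ± 0.55) and the cell cycle inhibitor CDKN1A (2.69-fold, log2 1.43 ± 0.30, adjusted p = 0.0469 in limma) rose. The list did not pass as a whole (camera adjusted p = 0.189), and 3 rose adjusted over it alone. TP53INP1 stood at 3.91 with the smaller and 2.06 with the larger of the other offsets. With the GAPDH ratio as a covariate neither passed, with adjusted p = 0.112 for TP53INP1 (log2 2.43) and 0.144 for CDKN1A (log2 1.405) in limma. Without both arrays of high ratio the log2 values were 2.56 and 1.46.

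Among genes of coagulation, those of fibrinolysis aside, none passed at day 7 over all genes tested. F3, which encodes tissue factor, the cellular starter of clotting, had a mean signal of 618 ± 206 (SD, n = 3) in irradiated and 291 ± 139 (SD, n = 2) in untreated cells. Its log2 fold change of 1.02 ± 0.40 did not pass (adjusted p = 0.351 in limma). The lowest irradiated array, replicate 2, had a signal of 390.5 and the highest untreated one, replicate 1, 389.3. Of 15 measured procoagulant factors and receptors, 0 passed over all genes and 1 rose adjusted over the list alone. That gene was FGL2, a cell surface protein with prothrombin-cleaving activity, at log2 1.74 ± 0.43 (adjusted p = 0.108 in limma). TGM2, a crosslinking enzyme, stood at 1.12 ± 0.63, and F13A1, the clot-crosslinking factor XIII subunit, at 0.81 ± 0.33. The list's mean was 0.37 and it did not pass (camera adjusted p = 0.0884). It passed camera at a mean signal of at least 300 (mean 0.48, adjusted p = 0.0358) and without irradiated day 7 replicate 2 (0.48, adjusted p = 0.0113). The list also passed with the run or joined runs as a block, a pairing that was not established. Without both arrays of high GAPDH ratio, chosen after seeing the data and resting on 1 irradiated day 7 array, its mean was 0.34. F5 lay below the signal minimum. SERPINB2 was not analysed here.

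Of 12 anticoagulant genes, 0 passed over all genes and 2 rose adjusted over the list alone, the protease inhibitor A2M (log2 1.78 ± 0.49) and the ectonucleotidase ENTPD1 (1.44 ± 0.32), of which 1 of 4 probe sets had the other sign. The list's mean was 0.50 (camera adjusted p = 0.0281, and adjusted p = 0.166 with an estimated correlation). THBD, which encodes thrombomodulin, stood at 0.57 ± 0.23, TFPI, the tissue factor pathway inhibitor, at -0.66 ± 0.55, PROCR at 0.19 ± 0.30 and ANXA5 at 0.28 ± 0.22, none past the threshold. Without both arrays of high GAPDH ratio, an alternative chosen after seeing the data, the mean of this list was 0.01 and A2M turned to -0.47.

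Of 8 fibrinolysis genes, 2 rose, S100A10 (3.46-fold, log2 1.79 ± 0.29) and ANXA2 (2.36-fold, log2 1.24 ± 0.25), whose products form a cell surface complex that binds plasminogen. Adjusted over the list alone 3 rose (mean 0.73, camera adjusted p = 0.00173, and adjusted p = 0.113 with an estimated correlation). PLAU, the urokinase gene, stood at 0.29 ± 0.36 and its receptor PLAUR at 0.56 ± 0.31. S100A10 still passed with the GAPDH ratio as a covariate (log2 1.69, adjusted p = 0.0283 in limma), and ANXA2 did not (1.35, adjusted p = 0.0525).

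**Figure D2:**
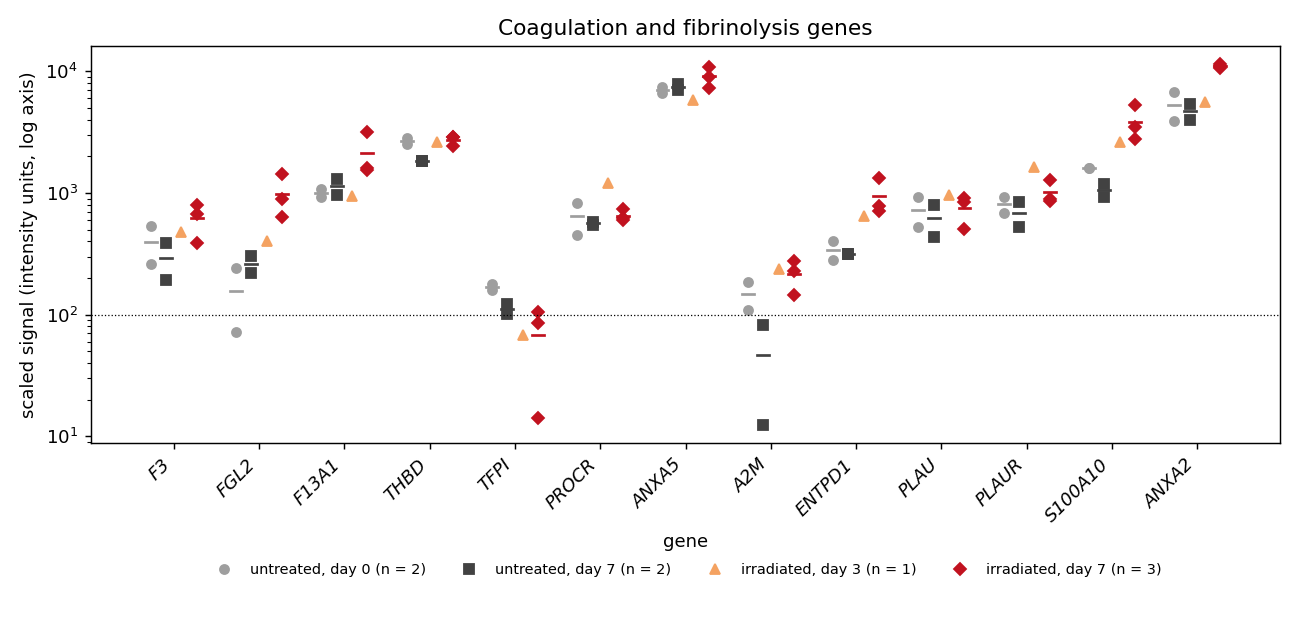
Scaled signal (log axis) of 13 coagulation and fibrinolysis genes on each of the 8 arrays, with points for arrays, bars for group means and a dotted line at 100. S100A10 and ANXA2 lie higher on the 3 irradiated day 7 arrays than on both untreated day 7 arrays and passed the test. For F3 the 3 irradiated day 7 arrays also lie above both untreated ones, the lowest of them by little, and F3 did not pass.

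Further lists had 1 or 0 genes past the threshold at day 7. VEGFA, an angiogenic growth factor on both the inflammatory and the hypoxia list, rose 2.37-fold, and 1 of its 4 probe sets had the other sign. It did not pass with the GAPDH ratio as a covariate (log2 1.13, adjusted p = 0.193 in limma) or without both arrays of high ratio (1.08, adjusted p = 0.383). VEGFA was the 1 of 22 inflammatory genes that rose, with 4 adjusted over the list alone (mean 0.55, camera adjusted p = 0.00326, and adjusted p = 0.2 with an estimated correlation), and the 1 of 28 glycolysis and hypoxia genes (camera adjusted p = 0.833). Of 15 MHC class I genes 0 passed and 4 rose adjusted over the list alone (mean 0.35, camera adjusted p = 0.00228, and adjusted p = 0.113 with an estimated correlation), with HLA-G at 0.83 ± 0.21 and TAP1 at 0.83 ± 0.24. Of 12 replication-dependent histone genes 0 passed and 3 rose adjusted over the list alone (mean 0.44, camera adjusted p = 0.0386, and adjusted p = 0.265 with an estimated correlation), with H2AC8 at 2.89-fold and H2AC6 at 2.84-fold. Ribosomal protein genes had a mean of 0.24 (camera adjusted p = 6.72e-06, and adjusted p = 0.46 with an estimated correlation), which turned to -0.02 under quantile normalization. RPL32 stood at 0.39 ± 0.16 and RPLP2 at 0.38 ± 0.61. Of 39 oxidative phosphorylation genes 0 passed (mean -0.15, camera adjusted p = 0.0064, and adjusted p = 0.619 with an estimated correlation), with CYC1 at -0.80 ± 0.31 and NDUFS1 at -0.58 ± 0.26.

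Lists that did not pass at day 7 were those of apoptosis regulators (camera adjusted p = 0.152, with TNFSF10 at 1.25 ± 0.29 and BCL2L1 at 1.19 ± 0.39), oxidative stress (0.0564, with HMOX1 at 2.39 ± 0.56 and GCLM at -1.09 ± 0.40), the unfolded protein response (0.886, with CHAC1 at -1.16 ± 0.53 and ATF3 at 0.92 ± 0.29) and cholesterol synthesis (0.485, with ACAT2 at -0.56 ± 0.28 and HSD17B7 at 0.50 ± 0.28). For the unfolded protein response the median (-0.03) and the mean (0.04) differed in sign. The immature myeloid list did not pass either (0.631), and MS4A3 was its 1 passing member. Markers of other cells showed no passing gene or list. The camera adjusted p was 0.319 for T cells, 0.65 for B cells, 0.432 for erythroid cells, 0.432 for megakaryocytes, 0.319 for fibroblasts and epithelium and 0.497 for endothelium. For the erythroid list the median was 0.02 and the mean -0.31. The members with the largest changes were CD8A (1.08) and CD3D (0.94), CD79B (0.56) and CD79A (0.44), KLF1 (-1.36) and HBB (0.09), GP6 (1.46) and GP9 (0.79), COL1A2 (0.97) and COL1A1 (0.33), and TEK (-1.59) and KDR (0.71). Probe sets of HLA-G, ATF3, BCL2L1, NDUFS1, RPLP2 and HBB disagreed in sign.

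In total 116 of 14649 genes changed at day 7, 112 higher and 4 lower. With the run as a block, a pairing that was not established, 544 were higher and 173 lower. Irradiated day 7 replicate 2 shares its run with no other array and does not bear on that result. Joined runs as the block gave 313 and 34, and the run as a random block 504 and 127. Without the trend of variance on signal, limma called 9 genes. It called 53, 66 and 471 without irradiated day 7 replicates 1, 2 and 3, and 74 and 43 without untreated day 7 replicates 1 and 2. With the GAPDH ratio as a covariate 97 genes were called, 76 of the 116 among them, and without both arrays of high ratio 64, with 52 of the 116.

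The comparison of all 4 irradiated with all 4 untreated arrays, whatever the day, called 146 genes, 132 higher and 14 lower. CFP (19.5-fold), IFI44L (15.5-fold), CD52 (12.4-fold), MX1 (9.82-fold), IFIT1 (9.40-fold) and IFI27 (9.09-fold) led the higher side. The lower side was led by DEFA4, a neutrophil defensin, at 4.42-fold, TEX15 (2.51-fold), POU4F2 (2.49-fold), VIT (2.25-fold), the metallothionein MT1E (2.21-fold) and LRRC34 (2.19-fold). Of the coagulation lists, FGL2 (3.57-fold, adjusted p = 0.039 in limma), ENTPD1 (2.42-fold) and S100A10 (2.59-fold) rose. The damage response genes CDKN1A (2.45-fold) and TNFRSF10B, a death receptor (2.01-fold), rose, though 2 of 3 probe sets of TNFRSF10B had the other sign. RRM2, a subunit of ribonucleotide reductase, fell 1.66-fold as the 1 passing gene of 40 S phase genes, of which 16 fell adjusted over the list alone (camera adjusted p = 3.09e-18, and adjusted p = 0.024 with an estimated correlation). CD14, the monocyte coreceptor for lipopolysaccharide, rose 3.70-fold, the haem-degrading enzyme HMOX1 4.58-fold, the chemokine CCL4 4.23-fold, the protease CTSB 2.96-fold, HLA-DMA 2.25-fold and FN1, fibronectin, 3.90-fold. For FN1, 1 of 5 probe sets had the other sign. Without irradiated day 7 replicate 2 another probe set had the highest mean, and the log2 value of FN1 was -1.06. Without both arrays of high GAPDH ratio 0 genes passed in limma, with 1153 at an unadjusted p under 0.05. That fit has 2 irradiated arrays fewer, and its log2 values were 3.78 for CFP, 2.75 for CD52, 3.22 for IFI44L, 1.53 for CTSB, 1.27 for CDKN1A, -1.25 for POU4F2 and -0.79 for FN1. With the ratio as a covariate 25 passed, among them CFP, CD52, POU4F2, CTSB and CD14 of the genes above. FGL2 (log2 1.58, adjusted p = 0.217 in limma), ENTPD1 (1.08, adjusted p = 0.13) and S100A10 (1.20, adjusted p = 0.0962) did not pass there. The count was 25 without irradiated day 7 replicate 1, 61 without replicate 2, 53 without untreated day 0 replicate 1, 62 without either untreated day 7 array and 267 without the day 3 array.

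Of the 30 lists 18 passed in that comparison, and 4 of these with an estimated correlation. Besides the S phase list they were maturation, with 8 of 33 genes higher and 21 adjusted over the list alone (mean 1.01, adjusted p = 0.024 with an estimated correlation), MHC class II, with 4 of 12 and 8 adjusted over the list alone (0.95, adjusted p = 0.0382 with an estimated correlation), and double-strand break repair, with 0 of 23 (-0.26, adjusted p = 0.0361 with an estimated correlation). Of 40 interferon genes 14 rose, and 31 adjusted over the list alone (mean 1.60, camera adjusted p = 1.39e-28, and adjusted p = 0.105 with an estimated correlation).

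The day 3 comparison set 1 irradiated array against the 2 untreated day 0 arrays. That array is assumed to vary like the other groups, so a deviation of its own is not separated from the difference between groups, and time in culture differs as well. ORM1, an acute phase protein, was 11.5-fold higher (log2 3.52 ± 0.37), TRIB3, a pseudokinase induced by stress in the endoplasmic reticulum, 6.70-fold (2.74 ± 0.35) and VEGFA 6.34-fold (2.67 ± 0.34). The histone genes H2BC9 and H2BC12L were 13.6-fold and 6.93-fold lower (log2 -3.76 ± 0.41 and -2.79 ± 0.40). These were the 5 genes called, with 760 at an unadjusted p under 0.05 where 732 would be expected by chance, and 0 were called without the trend or without untreated day 0 replicate 1. The count was 2 without untreated day 0 replicate 2 and 10 without irradiated day 7 replicate 3. LY6E (2.30), H2BC12 (-2.37) and MESP1 (-2.51), for which 1 of 3 probe sets had the other sign, are given as values. H2B genes are near-identical, so their single values are uncertain.

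Among the lists, 15 passed at day 3 with the preset correlation and 0 with an estimated one. Of 26 genes of the unfolded protein response, 23 had a positive log2 fold change and 1, TRIB3, rose (mean 0.75, camera adjusted p = 1.12e-11, and adjusted p = 0.0645 with an estimated correlation). Of 12 replication-dependent histone genes 1 fell, and 4 fell adjusted over the list alone (mean -1.01, camera adjusted p = 3.82e-06, and adjusted p = 0.0932 with an estimated correlation). No gene passed in the maturation list (mean 0.55, estimated-correlation adjusted p = 0.0645, with CD14 at 2.50 ± 0.50 and ITGAM at 1.94 ± 0.46), the lysosomal list (0.46, adjusted p = 0.183 with an estimated correlation, with CTSB at 1.37 ± 0.29 and CTSH at 1.13 ± 0.31), the S phase list (-0.37, adjusted p = 0.166 with an estimated correlation, with CCNE2 at -1.40 ± 0.32 and UNG at -1.32 ± 0.34) or the oxidative stress list (-0.43, adjusted p = 0.0645 with an estimated correlation, with MT1H at -2.03 ± 0.41 and HMOX1 at 1.93 ± 0.74). The interferon list did not pass (mean 0.20, camera adjusted p = 0.108), nor did the procoagulant (0.184) and anticoagulant (0.103) lists. The fibrinolysis list passed, with 7 of 8 genes positive and 0 passing (mean 0.58, camera adjusted p = 0.00827, and adjusted p = 0.166 with an estimated correlation), but not without untreated day 0 replicate 2 (0.51, adjusted p = 0.12). F3 stood at 0.31 ± 0.54, THBD at -0.04 ± 0.31, PLAUR at 1.01 ± 0.41 and FGL2 at 1.36 ± 0.58.

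**Figure D3:**
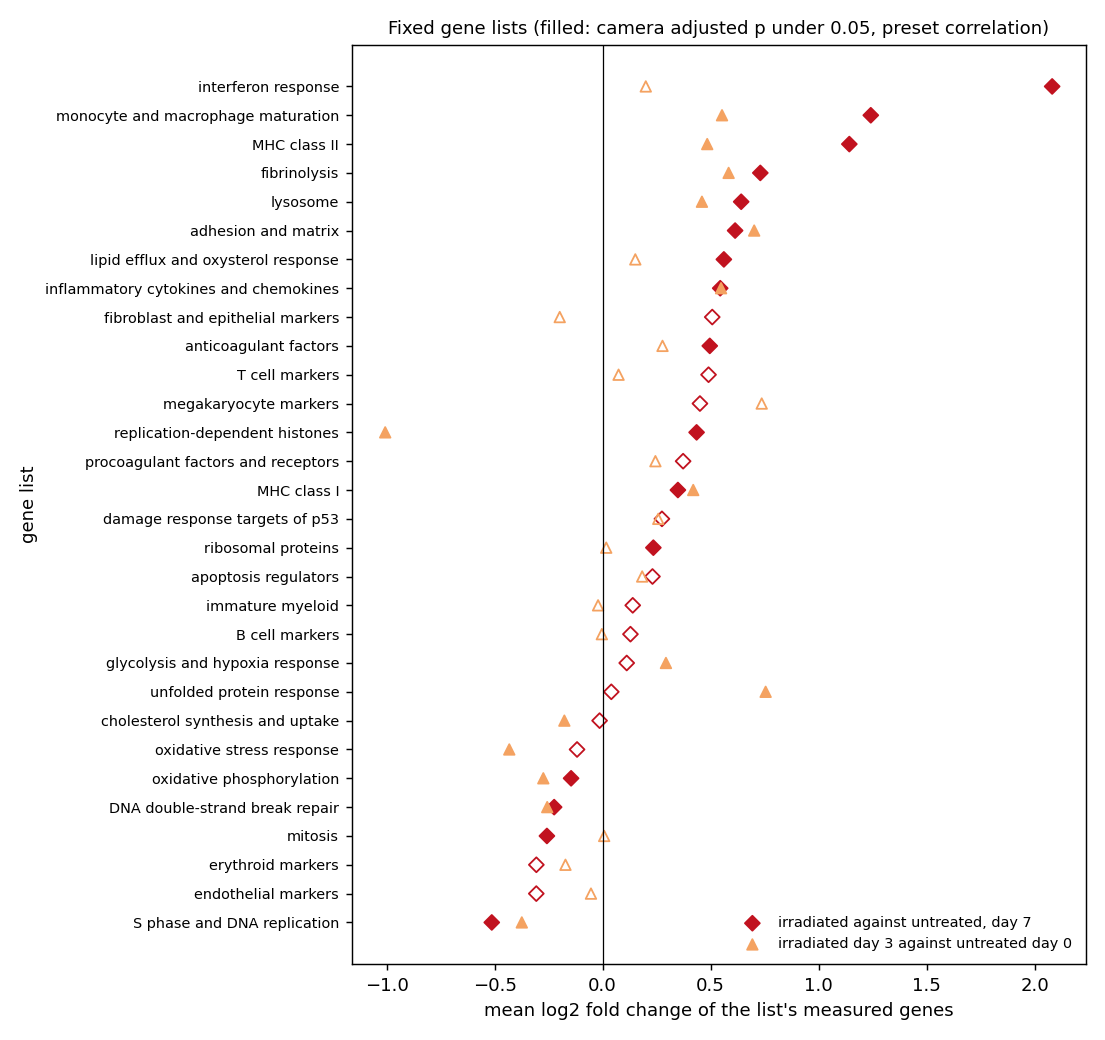
Mean log2 fold change of the measured genes of each of the 30 fixed lists (rows) in the day 7 comparison (diamonds) and the day 3 comparison (triangles). Filled symbols passed camera with its preset correlation. The interferon list lies at 2.08 at day 7 and 0.20 at day 3, and the histone list at 0.44 and -1.01.

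The responses at day 7 and day 3, which share no array, correlated across genes with Pearson's r = 0.21 and Spearman's rho = 0.225, where genes are not independent replicates. Of the 112 genes higher at day 7, 94 had a positive log2 fold change at day 3, against 50.2% of all genes. All 4 lower genes had a negative one. VEGFA was the 1 gene called at both days, though its day 7 call was lost with the GAPDH ratio as a covariate.

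In the test of the difference between the responses, 3 genes passed, H2BC9 (log2 3.77 ± 0.51), ISG15 (3.65 ± 0.45) and IFI44 (3.61 ± 0.48), each more positive at day 7. The day 3 side is 1 array, assumed to vary like the other groups. H2BC12 (3.31), TRIB3 (-2.33), SLC7A5 (-2.32), ORM1 (-2.22) and ALG1 (-2.02) are given as values. Of 40 interferon genes 2 passed and 27 passed adjusted over the list alone (mean 1.88, camera adjusted p = 8.43e-41, and adjusted p = 0.0835 with an estimated correlation). The count was 0 without the trend and on leaving out untreated day 7 replicate 2, either untreated day 0 array or irradiated day 7 replicate 2. It was 1, 5 and 6 without irradiated day 7 replicate 1, untreated day 7 replicate 1 and irradiated day 7 replicate 3. No procoagulant, anticoagulant or fibrinolysis gene passed, and those lists gave camera adjusted p = 0.764, 0.66 and 0.66. For fibrinolysis the median (-0.05) and the mean (0.15) differed in sign.

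In untreated cells, 7 days of culture changed 0 of 14649 genes in limma. At an unadjusted p under 0.05 there were 372 genes, fewer than the 732 expected by chance. Without the trend 0 were called as well, with 458 at that unadjusted p. In a fit of only the arrays compared 0 were called, with 615 at that unadjusted p. The low number of 372 thus depends in part on the spread of the irradiated arrays, which the main fit shares. As values, ZMAT5 (log2 1.70), SLC5A2 (2.03), MYRF-AS1 (1.42) and ARVCF (1.76) were the higher genes with the lowest p, and OXCT2 (-1.88), ZNF626 (-2.65), LINC01089 (-1.51) and MRNIP (-2.03) the lower ones. Of the 30 lists 9 passed camera and 0 did so with an estimated correlation. They included the lysosomal list (mean -0.29, adjusted p = 0.434 with an estimated correlation) and the maturation list (-0.24, adjusted p = 0.403 with an estimated correlation). The anticoagulant list (-0.33) passed camera too. The others were ribosomal proteins (-0.18), MHC class I (-0.24), adhesion and matrix (-0.17), immature myeloid (-0.23), cholesterol synthesis (-0.25) and fibroblast and epithelial markers (-0.84). For lists higher in irradiated than in untreated day 7 cells, such lower untreated day 7 values widen the difference. With 2 arrays on each side, simulated changes of 2-fold were recovered for 12% of genes and of 4-fold for 69.6%, so smaller changes were mostly not detectable.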

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

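The explanations weighed in this part, their bounds and the further searches were chosen only after the results were seen. The test of the difference between the days, the calls that are weighed and the alternatives without the GAPDH ratio were planned.

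The difference between the day 7 and the day 3 response passed for 3 genes, each more positive at day 7: H2BC9 at 3.77, ISG15 at 3.65 and IFI44 at 3.61 on the log2 scale. For 8 lists it passed camera with the preset correlation and for 0 of them with an estimated one. The mean differences were 1.88 for interferon response, 1.44 for replication-dependent histones, 0.69 for monocyte and macrophage maturation, 0.66 for MHC class II, 0.31 for oxidative stress response, 0.22 for ribosomal proteins, -0.27 for mitosis and -0.71 for the unfolded protein response. The day 3 side of each rests on 1 array.

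The rise of the interferon list at day 7 was weighed against 3 technical explanations. RNA quality would need the list to lose its rise once the GAPDH ratio is a covariate, yet its mean was then 2.50 and it still passed camera with the preset correlation. The ratio differed much only among the irradiated day 7 arrays, so this check rests largely on replicate 3, the array of low ratio. Against the untreated day 7 arrays, that array had medians of 2.35 and 2.27. One deviating array would need a small difference on the others, yet the lowest of the 6 medians between an irradiated and an untreated day 7 array was 1.46. Differences between runs would need the rise to be absent within a run, yet the medians were 1.46 and 2.27 within the 2 runs, marked by shared title prefixes, that hold both groups. The list's call was lost with an estimated correlation (adjusted p = 0.0772) and kept by fry (adjusted p = 0.00733). A response to irradiation stays a hypothesis, found and tested on the same data.

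Of the 116 genes called at day 7, 96.6% were higher, while at an unadjusted p under 0.05 in limma 1142 genes were higher and 588 lower. Scaling of the arrays would need this share to fall under another scaling, and the lowest of the 3 alternatives was 93.0%. RNA quality would need it to fall with the ratio as a covariate, and it was 91.8%. Scaling thus does not account for the direction. The covariate, chosen after seeing the data, rests largely on irradiated day 7 replicate 3 and does not settle RNA quality. With it, 40 of the 116 calls were not made. The share that was higher was 75.9% with the run as a block, 90.2% with joined runs and 79.9% with the run as a random block. Its size thus depends on whether arrays are paired by run, which was neither established nor excluded. Without irradiated day 7 replicate 3, the array of low ratio, 471 genes were called and 73.5% were higher.

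The histone list was lower on the day 3 array. RNA quality would need a raised ratio on that array, and it was 1.21, inside the range of the untreated arrays. Signal shared between near-identical histone genes cannot be told apart from separate falls: the 7 probe sets whose names mark no shared sequence had a median of -1.19, but only 5 of the 7 were lower. With 1 array at day 3, an array that deviates by itself also stays open, as does an effect of irradiation.

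In the comparison of all irradiated with all untreated arrays, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave at least 146 genes, so chance can be excluded at a share under 0.05 only if arrays are exchangeable between runs. The highest other split gave 120 genes and the remaining 33 gave 0. That split exchanges irradiated day 7 replicate 3 with untreated day 0 replicate 2, so it keeps 3 of the 4 irradiated arrays on one side, among them both with a GAPDH ratio above 3. The 13 further splits that keep those 2 arrays on one side gave 0 genes. Each of them also mixes irradiated with untreated arrays, so an effect of irradiation would widen the spread within its sides. Their 0 calls therefore do not exclude RNA quality. Only 12 splits keep equal parts of each joined run on both sides, too few for a share under 0.05, and of these the real one gave 146 genes and the other 11 gave 0.

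In the search for single arrays far from the 3 others of their side, 36 groups of values were tested and chance alone gives about 1.8 flags. CD52 had a signal of 1294 on the day 3 array, far below the 3 irradiated day 7 arrays, and POU4F2 had 4618 on untreated day 0 replicate 2, above the other untreated arrays. The genes searched were those named in the comparison of all irradiated with all untreated arrays. The day 3 array was grouped with the day 7 arrays, so the CD52 flag is not separated from a difference between the days. Among 7089 probe sets without a single gene symbol, which the comparisons by gene did not use, 8 were called higher at day 7 and 0 lower.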

How the results depend on the processing

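The alternatives with the GAPDH 3' to 5' ratio, as a covariate or with both arrays of high ratio left out, were chosen after seeing the data. Of 3962 values of named genes under the alternatives, 3360 kept their direction and side of the threshold, 406 kept only the direction and lost the call, 149 gained a call and 47 changed sign. The cause of the changes was not tested unless the construction of an alternative shows it. The number of arrays and the lack of detection calls limit what low signals can show.

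The count of genes changed at day 7, 116 as reported, was 72 with no filter, 58 for all probe sets, 62 for the mean of a gene's probe sets, 9 without the trend, 193 at an adjusted p under 0.10, 262 with all 4 untreated arrays as the control, and 64 without both arrays of high ratio. For all irradiated against all untreated, 146 as reported, it was 32 for all probe sets, 59 for the mean of probe sets, 27 without the trend, 274 at an adjusted p under 0.10, 267 without the day 3 array, 25 with the covariate and 0 without both arrays of high ratio, where limma gave 1153 at an unadjusted p under 0.05. For day 3, 5 as reported, it was 0 for all probe sets, 2 for the mean of probe sets, 0 without the trend, 48 in a fit of only the arrays compared and 10 with the covariate. For the difference between the responses, 3 as reported, it was 1 with no filter, 0 for all probe sets, 0 without the trend and 17 with the covariate. Tests over all probe sets or with no filter adjust over more tests. Leaving out each array in turn gave 43 to 471 genes at day 7, 25 to 267 for all irradiated against all untreated, 0 to 10 at day 3 and 0 to 6 for the difference. Where this left a group with 1 array, it was assumed to vary like the other groups. The untreated comparison gave 0 genes in limma in every alternative run, with 153 (of 9096 genes) to 1132 (of 35129 probe sets) at an unadjusted p under 0.05.

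With the run as a replicate block, 717 genes were called at day 7, 54 at day 3, 50 for the difference and 160 for all irradiated against all untreated, with 94 of the 146 reported genes among these, and the untreated comparison could not be estimated. With joined runs as the block the counts were 347, 21 and 14, with 450 for all irradiated against all untreated, and with the run as a random block 631, 52 and 42, with 647. Irradiated day 7 replicate 2 and untreated day 0 replicate 1 share a run with no other array. With the run as a replicate block they therefore do not bear on the differences between groups. At day 3 that fit compares the irradiated array with untreated day 0 replicate 2 only. It also leaves fewer residual degrees of freedom than the reported fits. The pairing by run was neither established nor excluded. The labels do not state it, and only 2 pairs of day 7 arrays share a run. Their correlations of deviations from the group means were 0.14 and 0.27. Irradiated day 7 replicate 2, of another run, had 0.15 with untreated day 7 replicate 1. Deviations of 2 untreated arrays from their own mean are mirror images, and those of the irradiated arrays are tied to each other. These correlations therefore cannot decide for or against pairing. At day 7 the higher and lower calls were 544 and 173 with the run block, 313 and 34 with joined runs and 504 and 127 with the random block, against 112 and 4 as reported. The share of called genes that were higher was 75.9% with the run block, 79.9% with the random block and 73.5% without irradiated day 7 replicate 3, against 96.6% as reported. The median log2 fold change of all genes at day 7 was 0.05, and -0.07 when arrays were centred on the median.

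The correlation across genes between the day 7 and day 3 responses, 0.21 as reported, was 0.38 among genes with a mean signal of at least 300 and 0.0686 over all probe sets. With an estimated correlation the day 7 calls of the anticoagulant (mean 0.50), fibrinolysis (0.73), S phase (-0.51), interferon (2.08) and lysosomal (0.64) lists were lost with their means as reported, and that of the anticoagulant list also by fry (0.50, adjusted p = 0.065). The estimated correlation of the anticoagulant list was -0.013, below the preset 0.01, so a higher correlation was not what cost it the call. Maturation at day 7 had an estimate of -0.0081, also below the preset, yet its unadjusted camera p rose from 3.77e-19 to 0.000504. By fry the interferon (adjusted p = 0.00733), S phase (0.0166), lysosomal (0.0185) and fibrinolysis (0.0371) lists still passed at day 7. The anticoagulant list also lost its camera call at a mean signal of at least 300 (0.37), for the mean of probe sets (0.37), against all 4 untreated arrays (0.33), against the day 0 arrays (0.17), with the covariate (0.25) and without both arrays of high ratio (0.014), with adjusted p between 0.051 and 0.542 in camera. The procoagulant list passed at a mean signal of at least 300 (0.48), with the run block (0.42), with joined runs (0.40) and without both arrays of high ratio (0.34), with adjusted p between 0.00852 and 0.0358 in camera. Leaving out each array gave means of 0.29 to 0.63 for the anticoagulant list, which did not pass in 4 of these fits, and 0.22 to 0.48 for the procoagulant list, which passed without irradiated day 7 replicate 2.

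Changes of sign were near 0 for most genes. At day 7 MKI67 was -0.065 with values as deposited, -0.11 centred on the median, -0.23 for the mean of probe sets, -0.14, -0.12 and -0.068 with the 3 blocks, -0.097 with the covariate and -0.11 without both arrays of high ratio. HBB was -0.040 under quantile normalization, -0.031 centred on the median, -0.23 for the mean of probe sets, -0.30, -0.22 and -0.11 with the blocks, -0.038 against day 0, -0.38 with the covariate and -0.40 without both arrays. RPLP2 was -0.40 for the mean of probe sets and -0.0092 with joined runs. Against the day 0 arrays TGM2 was -0.0075, HSD17B7 -0.038, GP6 -0.11, COL1A2 -0.37, COL1A1 -0.10 and TEK 0.031. PLAU was -0.29 with the covariate and -0.21 without both arrays, and CD79A -0.0094 and -0.13. Without both arrays A2M was -0.47, RAD51D 0.17 and, for all irradiated against all untreated, FN1 -0.79, where another probe set of FN1 had the highest mean. At day 3 THBD was 0.14 for the mean of probe sets, and F3 -0.16 with the run block and -0.21 with joined runs. Leaving out each array gave -0.15 to 1.58 for KDR, -0.22 to 0.40 for HBB, -0.14 to 0.094 for MKI67, -0.12 to 0.70 for PLAU, -0.22 to 0.88 for COL1A1, -1.06 to 2.12 for FN1 and, at day 3, -0.16 to 0.79 for F3 and -0.12 to 0.033 for THBD.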

Other observations

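Further lists were compared between the day 3 array and the untreated day 0 arrays, and all but the last passed camera only with the preset correlation. Of 35 adhesion and matrix genes 32 had a positive log2 fold change, 0 passed and 1 rose adjusted over the list alone (mean 0.70, camera adjusted p = 4.28e-11, and adjusted p = 0.104 with an estimated correlation). Of 15 MHC class I genes 13 had a positive one and 4 rose adjusted over the list alone (mean 0.42, camera adjusted p = 8.69e-05, and adjusted p = 0.0932 with an estimated correlation). Of 39 oxidative phosphorylation genes 35 had a negative one and 0 passed (mean -0.27, camera adjusted p = 2.14e-05, and adjusted p = 0.432 with an estimated correlation). The lists of MHC class II (mean 0.48, camera adjusted p = 0.00117), inflammatory genes (0.55, adjusted p = 0.0038), double-strand break repair (-0.26, adjusted p = 0.00548), glycolysis and hypoxia (0.29, adjusted p = 0.0303) and cholesterol synthesis (-0.18, adjusted p = 0.0463) had adjusted p = 0.101, 0.219, 0.104, 0.25 and 0.432 with an estimated correlation. Ribosomal proteins did not pass (camera adjusted p = 0.504) and had a mean of 0.02, which was -0.10 under quantile normalization.

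Among the 112 genes higher at day 7, the 25 on the interferon list had a median day 3 log2 fold change of 0.29, with 17 of 25 positive. The 87 outside it had 0.80, with 77 of 87 positive.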
